A study of Homo sapiens with 4 samples.

How the data were processed

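Chromatin of MCF7 cells was digested with micrococcal nuclease and precipitated with in-house antibodies, per the labels' protocols. The 4 libraries fall into 4 groups of 1: RDMe1 ChIP, input DNA, and H4R3me2a ChIP from control and RDMe1 knockdown cells. The knockdown was made with lentivirus. Only a peak list of the RDMe1 ChIP was analysed, and values of the other 3 libraries were not analysed here.

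The peak list gives the chromosome, start, end, name and score of each peak. The submitters' processing notes name Bowtie2 2.2.6, SAMtools, deepTools 1.5.12 and MACS 1.4.2, and the builds hg19 and GRCh37, which share the coordinates of the nuclear chromosomes. The role of each tool, the peak calling settings, the read filters and whether the input library served as the control are not given in the sources used here. The score of each peak was used as deposited by the authors, whose notes name MACS for the processing, and the list has no header that states its scale. It was read as −10 log10 of the peak's p-value, because the peak names start with MACS and the values start at 50 and stop at 3100 for 3 peaks. The peaks come from 1 library, so no replicates were pooled. No peaks overlapped, and all lay on chromosomes 1 to 22, X and Y. A peak caller made for narrow peaks can split a broad enriched region into several peaks, and can extend a strong one, so numbers and widths depend on its settings. The number of peaks also depends on the read depth, which is unknown. Positions are printed counting from 1.

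The reference table used was a list of RefSeq genes of assembly GRCh38.p14, a build other than that of the peaks. On 12 of the chromosomes 1 to 22 and X, peaks ended beyond the last gene of that table. It was used only for the number of protein-coding gene symbols per chromosome, and no coordinates were taken from it or converted. Peaks are therefore described by position and not by gene. The planned results on promoters, annotation classes, gene lists (marker genes of cell types among them), sequence composition and motifs need the hg19 genome and were not run.

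From the list were computed the widths, the gap to the nearest peak and counts per chromosome and per 1 Mb bin (by peak start). Blocks of 1 or more adjacent bins with at least 20 peaks each were also listed. Density per chromosome was taken between its first and last peak, since chromosome lengths were not used. This raises the density of a chromosome whose ends hold no peak, and chromosome Y, with 1 peak, was left out of it. Counts per chromosome have exact Poisson 95% intervals, shares have Wilson 95% intervals, medians have distribution-free 95% intervals and the correlation of score and width has a percentile interval from 1000 bootstrap resamples. Ratios of peaks per gene between 2 chromosomes have a percentile interval from 1000 resamples of the 1 Mb bins of each chromosome. This was added after the counts had been seen, because the Poisson intervals ignore the grouping of peaks, and was run for 16 over 10, 16 over 4 and 17 over 4. Observed clustering was set beside 1000 random placements (seed 20). These kept the widths and the number of peaks per chromosome, put the peaks without overlap between the first and last peak, and, unlike the plan, did not leave out assembly gaps. With 1 library no test between groups was possible, and no p-value was computed across peaks. The clustering measure was tested on 20 simulated sets of 18582 uniformly placed peaks, and all 20 fell inside the range of their random placements. These sets were drawn in the same way as the placements. The result therefore checks the calculation only, and not whether uniform placement suits real peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

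Before the data were examined, the named peaks were fixed as the 25 with the highest score, the 10 widest and the 5 bins of 1 Mb with the most peaks. The alternatives fixed then were peaks at or above the median score, peaks with a score of at least 100, the list without chromosomes M (which held no peak) and Y, the list without chromosomes 1, 17 and 20 (parts of which are known to be gained in MCF7), peaks closer than 1 kb merged, neighbour distances of 1 and 50 kb, covered sequence in place of peak number, and the list without the top 1% of scores. Alternatives added after the data were seen were peaks per protein-coding gene, placement inside the own 1 Mb bin (of the peaks as listed and as merged at 1 kb), bins starting at 0.5 Mb, peaks closer than 5 kb merged, the list without peaks in the first 25 kb of a chromosome, merging at 1 kb for the clustering and the score correlation, and peaks at or above the median score for the score correlation.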

Results

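The study profiled MCF7 cells, an established estrogen receptor-positive human breast cancer line, by chromatin immunoprecipitation and sequencing. It asked where the protein named RDMe1 lies on chromatin, and whether RDMe1 knockdown changes H4R3me2a, the asymmetric dimethylation of arginine 3 of histone H4. That mark is known to be deposited mainly by the methyltransferase PRMT1. The 4 libraries comprised 1 RDMe1 ChIP, 1 input DNA, 1 H4R3me2a ChIP from cells with a control shRNA and 1 H4R3me2a ChIP from cells with an shRNA against RDMe1. Only the RDMe1 ChIP peak list was analysed here. The comparison of H4R3me2a between control and knockdown cells was therefore not analysed. With 1 library there were no replicates, and each value below describes that library alone. The intervals cover counting error only, and those of shares and medians also ignore the grouping of peaks. The read depth behind the peaks is unknown.

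RDMe1 enrichment in MCF7 chromatin was listed as 18583 peaks, which together covered 32.9 Mb of the hg19 genome. The peaks lay on all 22 autosomes and on X, and 1 was listed on Y, at 234082 to 234897. The first peak on X started at a similar position, 284085. Whether the reads of the Y peak came from Y was not tested, so it is not taken as binding there. Their median width was 1161 bp (95% interval of the median 1151 to 1172 bp), and the widths ranged from 413 to 54685 bp. The median score was 81.0 (95% interval 80.2 to 81.8). The score is the authors' own value per peak, read here as being on the −10 log10 p scale of MACS, so that the lowest score of 50 stands for p = 1e-05. A score of at least 100 was reached by 6657 peaks, or 35.8% of the list, and a score of at least 1000 by 111 peaks. Peaks wider than 10 kb numbered 231 and held 11.2% of all covered sequence.

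The highest scores fell on broad intervals of several chromosomes. The score is not a fold enrichment, and none was analysed here. The highest score in the list, 3100, was shared by 3 peaks and is a ceiling, so these 3 cannot be ranked against each other. One of them spanned 29983 bp of chromosome 11 (65251884 to 65281866). Another spanned 18454 bp of chromosome 7 (5551830 to 5570283), and the last spanned 8661 bp of chromosome 17 (79471285 to 79479945). Below the ceiling, a peak on chromosome 5 (172188807 to 172199762) scored 2860.65. It was followed by peaks on chromosome 14 (70231988 to 70248898) with a score of 2635.24 and on chromosome 21 (41751840 to 41762767) with 2376.91. A peak on chromosome 17 (7473407 to 7486507) scored 2331.58, and one near the end of chromosome 14 (105941192 to 105957459) scored 2302.66. Chromosome 5 carried another high-scoring peak (179030403 to 179050763) with a score of 2195.27, and chromosome 19 one (45969549 to 45985443) with 2164.67.

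Among the 25 peaks with the highest scores, 5 lay on chromosome 14, 4 on chromosome 12, 4 on chromosome 17 and 3 on chromosome 5. The remaining 9 were spread over 7 other chromosomes. Each of the 25 scored at least 1731.04, and their widths ran from 6258 to 33586 bp, with a median of 16268 bp. On chromosome 11, the peak of 33586 bp (65181138 to 65214723, score 2091.81) lay close to the one at the ceiling. On chromosome 14, neighbouring peaks at 75714339 to 75735310 (score 1894.06) and 75735445 to 75763123 (score 2058.55) were both in this set. Chromosome 13, which held only 44 peaks in all, contributed 1 of the 25 (45905968 to 45915726, score 2119.63).

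The widest peaks were mostly other intervals than the highest scoring ones. The widest covered 54685 bp of chromosome 17 (62484812 to 62539496) and scored 1100.6. It was followed by intervals of 46896 bp on chromosome 1 (151146592 to 151193487, score 128.37), 44268 bp on chromosome 5 (177540722 to 177584989, score 178.81) and 42845 bp on chromosome 8 (101920874 to 101963718, score 577). Only 1 of the 10 widest peaks, the one at 65181138 on chromosome 11, was also among the 25 highest scores. A peak of 35450 bp on chromosome 8 (128856114 to 128891563) scored 69.13, below the median of the list. Of the 10 widest, chromosome 1 held 2, and chromosomes 17 and 20 held 1 each. Parts of these chromosomes are known to be gained in MCF7. The others lay on chromosomes 5, 8, 11 and 12. Copy number was not analysed here, so its share in these widths is unknown.

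Across the whole list, wider peaks nevertheless had higher scores. Score and width come from the same peak call, which can extend a strong peak, so this relation may arise in the calling. The 4646 peaks of the highest score quartile had a median width of 2447 bp, against 743 bp for the 4646 peaks of the lowest. Spearman's rho between score and width across peaks was 0.79 (95% bootstrap interval 0.782 to 0.796). Within single chromosomes rho lay between 0.70 and 0.91. Peaks are not independent replicates, so no p-value is attached to these correlations. For the same reason the bootstrap interval is too narrow to the extent that neighbouring peaks resemble each other.

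Chromosomes 17, 16 and 19 held the most peaks for their length. Chromosome 17 carried 2277 peaks, or 28.3 per Mb between its first and last peak (exact Poisson 95% interval 27.1 to 29.5). Chromosome 19 carried 26.2 per Mb (24.96 to 27.6) and chromosome 16 carried 22.1 per Mb (21.1 to 23.05). These 3 chromosomes together held 31.3% of the peaks and 17.4% of the protein-coding genes. At the other end, chromosome 4 had 0.44 peaks per Mb (0.35 to 0.54), chromosome X 0.45 (0.35 to 0.57), chromosome 13 0.47 (0.34 to 0.63) and chromosome 18 0.67 (0.48 to 0.91). These 4 chromosomes held 238 peaks, or 1.28% of the list, against 11.1% of the protein-coding genes. Over chromosomes 1 to 22 and X the density was 6.43 peaks per Mb.

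Chromosomes with more protein-coding genes held more peaks over the 23 chromosomes compared (Pearson's r = 0.62, Spearman's rho = 0.61). Without chromosomes 1 and 21, which lie farthest from the median gene number, r was 0.56 and rho 0.55. Counted per gene, chromosome 19 was close to the mean, with 1.06 peaks per protein-coding gene (exact Poisson 95% interval 1.01 to 1.12) against 0.93 overall. Chromosome 16 had 2.33 peaks per gene (2.23 to 2.43), chromosome 14 had 2.21 (2.09 to 2.33) and chromosome 17 had 1.95 (1.87 to 2.03). Of these 23 chromosomes, the fewest were on X with 0.081 (0.063 to 0.103), chromosome 4 with 0.109 (0.087 to 0.135), chromosome 13 with 0.130 (0.095 to 0.175) and chromosome 18 with 0.152 (0.109 to 0.206), followed by chromosome 10 with 0.28 (0.24 to 0.32) and chromosome 22 with 0.33 (0.28 to 0.38). These intervals treat peaks as independent and are too narrow to the extent that peaks lie in groups. The variance of the counts per 1 Mb bin was 70.2 times their mean, where independent peaks at 1 common density would give a ratio near 1. Chromosome 16 carried 21.3 times as many peaks per gene as chromosome 4, the lowest autosome, with a 95% interval of 9.66 to 58.1 when whole 1 Mb bins were resampled within each chromosome. Over chromosome 10 the ratio was 8.29 (4.40 to 16.1). These pairs and this interval were chosen after the counts had been seen, and the intervals are not corrected for that choice. Bins were resampled singly although dense bins lie in runs, so these intervals too may be too narrow. Chromosomes of 1 library are not replicates, so no p-value is given for the comparisons between them.

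**Figure D1:**
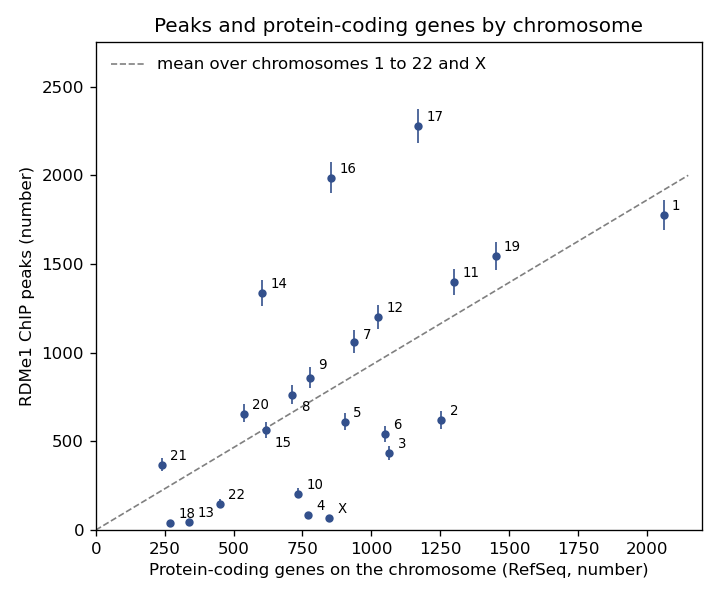
Number of RDMe1 ChIP peaks (vertical axis) against the number of protein-coding RefSeq genes (horizontal axis) for chromosomes 1 to 22 and X of 1 library. Points are chromosomes, bars are exact Poisson 95% intervals, and the dashed line is the mean of 0.93 peaks per gene. Chromosomes 14, 16 and 17 lie above the line, and chromosomes 4, 10 and X lie below it.

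Within chromosomes the peaks were concentrated in a small part of the sequence. Of 2908 bins of 1 Mb between the first and last peak of each chromosome, 2003 (68.9%) held no peak, and 89 bins (3.06%) held 50% of all peaks. In 1000 random redistributions of the peaks over the bins of their own chromosome, between 471 and 483 bins were needed for that share. The bin from 65 to 66 Mb of chromosome 11 held the most peaks, 246, and its neighbour from 66 to 67 Mb held 225. Peaks covered 666 kb and 616 kb of these bins. The next 3 bins were all on chromosome 16, at 2 to 3 Mb with 219 peaks, at 30 to 31 Mb with 201 peaks and at 0 to 1 Mb with 200 peaks.

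Blocks of 1 or more adjacent bins with at least 20 peaks each, a limit chosen after the values were seen, numbered 121. They held 82.0% of the peaks in 8.94% of the bins, and many were single bins. The largest block ran from 61 to 72 Mb on the long arm of chromosome 11 and held 1038 peaks. The end of the long arm of chromosome 17, from 72 to 82 Mb, held 780 peaks, and the tip of the short arm of chromosome 16, from 0 to 5 Mb, held 763. Further blocks lay at 144 to 152 Mb of chromosome 1 with 519 peaks, at 10 to 17 Mb of chromosome 19 with 504, at 45 to 51 Mb of chromosome 19 with 472 and at 102 to 106 Mb of chromosome 14 with 428. Of the 25 highest scoring peaks, 20 lay in such blocks, a share close to the 82.0% of all peaks. Chromosomes 13 and Y had no bin with as many peaks. Parts of chromosomes 1, 17 and 20 are known to be gained in MCF7, and copy number was not analysed here. Its share in the dense blocks is therefore unknown.

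Long stretches of the genome carried no peak at all. Intervals over 10 Mb between neighbouring peaks numbered 62 and made up 45.0% of the sequence between the first and last peaks. The longest, of 67.8 Mb, lay on chromosome 13 (46101899 to 113930018), followed by 57.8 Mb on chromosome 4 (83817607 to 141582334) and 49.4 Mb on chromosome X (53573577 to 102934684). On chromosome 16, 35.7 Mb from 31498247 to 67194004 separated blocks of dense peaks on either side. Some of these intervals include centromeres and other assembly gaps, which were not masked here. Read depth is unknown and copy number was not analysed, so an interval without a peak does not show absence of RDMe1.

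**Figure D2:**
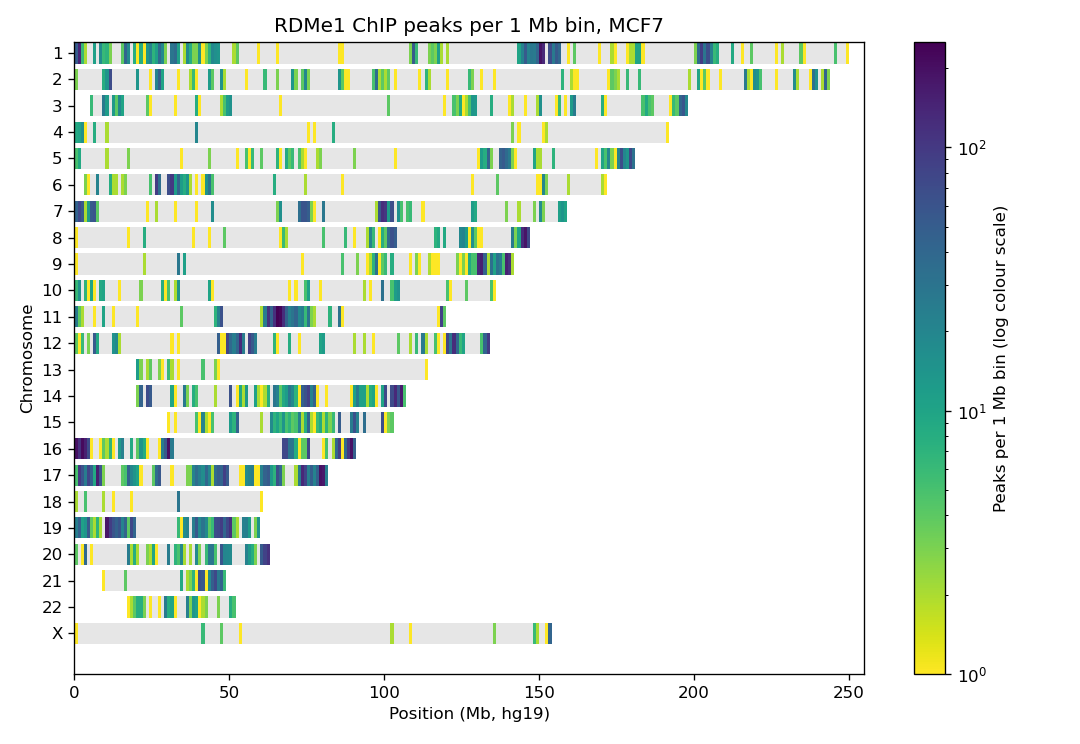
RDMe1 ChIP peaks per 1 Mb bin along chromosomes 1 to 22 and X (vertical axis), by hg19 position in Mb (horizontal axis), in 1 library. Colour gives the number of peaks on a log scale, and grey marks bins with no peak between the first and last peak. The darkest bins include 65 to 67 Mb of chromosome 11 (246 and 225 peaks) and 2 to 3 Mb and 0 to 1 Mb of chromosome 16 (219 and 200 peaks).

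At the scale of kilobases, neighbouring peaks lay close together. The median gap between neighbours was 2079 bp, and 6609 of 18559 gaps (35.6%) were under 1 kb. A neighbour within 5 kb was found for 15180 peaks, or 81.7% (Wilson 95% interval 81.1 to 82.2). In 1000 random placements of the same peaks along their chromosomes this share was between 11.5% and 13.8%, with a mean of 12.5%, so that the observed share was 6.53 times the random mean. When each peak was instead placed at random inside its own 1 Mb bin, which keeps the dense blocks dense, the share was between 51.6% and 53.7%. No random placement of either kind reached the observed share.

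**Figure D3:**
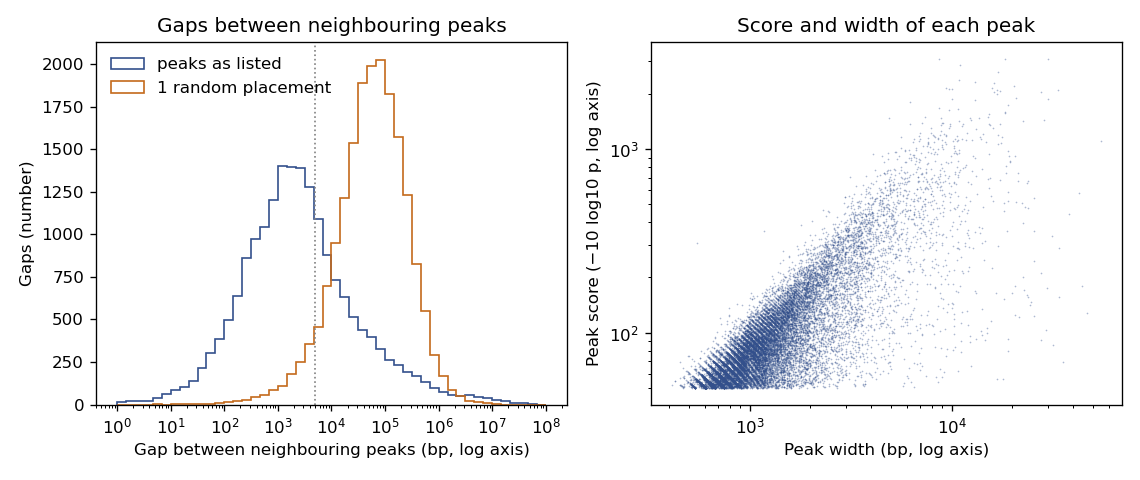
Left, number of gaps (vertical axis) by gap length in bp (horizontal log axis) between neighbouring RDMe1 ChIP peaks as listed and in 1 random placement; the dotted line marks 5 kb, and the listed gaps have a median of 2079 bp. Right, score on the −10 log10 p scale (vertical log axis) against width in bp (horizontal log axis), with 1 point per peak and a rho of 0.79.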

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

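With 1 library, no replicate could be left out and no call rests on a test, so an alternative is compared with the counting interval of a value or, for counts, with a factor of 1.5. No result changed direction. The number of peaks was 9294 at or above the median score, 6657 at a score of at least 100, 11974 after merging peaks closer than 1 kb and 6262 after merging those closer than 5 kb. For the same 4 lists the median width was 1672.5, 2003, 1239 and 1810 bp, and without chromosomes 1, 17 and 20 it was 1125 bp, against 1161 bp. The covered sequence fell from 32.9 to 19.9 Mb at a score of at least 100 and stayed within a factor of 1.5 under the other 5 alternatives run. The share of peaks with a neighbour within 5 kb was 78.7% at or above the median score, 77.1% at a score of at least 100 and 66.8% after merging at 1 kb, and with distances of 1 and 50 kb it was 52.8% and 95.6%. The fold over random placements was 11.5, 15.5 and 8.13 for the same 3 lists, 7.34 without chromosomes 1, 17 and 20, and 19.6 and 1.49 for the distances of 1 and 50 kb. It was 1.55 when peaks were placed inside their own 1 Mb bin, and 1.67 when peaks merged at 1 kb were. The number of bins holding 50% of the peaks stayed within a factor of 1.5 of 89 under all 6 alternatives run.

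Relative to chromosomes 1 to 22 and X, chromosome 17 had 4.40 times the density. This became 4.22 at a score of at least 100, 5.03 by covered sequence and 2.09 per protein-coding gene. For chromosome 19 the main value was 4.08, and it became 3.46 at or above the median score, 3.11 at a score of at least 100, 4.52 after merging at 1 kb, 2.78 by covered sequence and 1.14 per gene. Chromosome 16 moved from 3.43 to 3.24 after merging, 3.03 by covered sequence and 2.5005 per gene. Chromosome 4 moved from 0.0684 to 0.0477 at or above the median score, 0.0291 at a score of at least 100, 0.0922 after merging, 0.0353 by covered sequence and 0.117 per gene. Chromosome 19 thus stayed well above the average per Mb by either measure and came near it per gene. The rho of score and width was 0.815 without chromosomes 1, 17 and 20, 0.799 after merging at 1 kb and 0.754 at or above the median score. Alternatives for promoters, annotation classes, gene lists, sequence composition and motifs were not run.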

Other observations

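The tests of copy number and gene number between chromosomes, both tests of clustering and the alternatives named as added were chosen after peak counts and gap lengths had been seen; the test of variance between bins was chosen after the counts had been seen but before its value was computed.

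Peaks with close neighbours had higher scores and were wider than isolated ones. The 15180 peaks with a neighbour within 5 kb had a median score of 87.6 (95% interval 86.7 to 88.6) and a median width of 1245.5 bp (1232 to 1261), and 41.3% of them scored at least 100. The 513 peaks with no other peak within 100 kb had a median score of 60.3 (58.7 to 62.1) and a median width of 788 bp (759 to 820), and 9.94% of them scored at least 100. Neighbouring peaks also resembled each other in score when they were close. Spearman's rho between the scores of neighbours was 0.27 over 6609 pairs less than 1 kb apart, 0.15 over 5712 pairs 1 to 5 kb apart, 0.07 over 4775 pairs 5 to 100 kb apart and -0.02 over 1463 pairs farther apart. These correlations are across peaks of 1 library, which are not replicates. Among chromosomes, 20 had the widest peaks, with a median of 1924.5 bp, and 13 the narrowest, with 734.5 bp. Parts of chromosome 20 are known to be gained in MCF7. Copy number was not analysed here, so its share in these widths is unknown.

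A small set of peaks was listed at the very start of chromosomes. The first peaks of chromosomes 1, 4, 5 and 18 started at nearly the same position, at 9844, 9853, 9868 and 9896. In the first 25 kb of the chromosome numbering, 9 peaks were listed on 8 chromosomes, with scores from 51.8 to 460. The highest scores were on chromosome 5 (9868 to 12305, score 460.19) and chromosome 1 (11487 to 15662, score 258.98). Of the 9, only 2 had a peak outside that window within 100 kb, and on chromosome 9 the next peak was 22092 kb away. Without these 9 peaks, the share of peaks with a neighbour within 5 kb was 81.7%. Assembly gaps and repeated sequence were not masked here, so these peaks cannot be taken as RDMe1 binding at chromosome ends.

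The concentration of peaks in few 1 Mb bins was not mainly a difference between whole chromosomes. Chromosome accounted for 15.4% of the variance of the log2 of the bin counts (with 1 added), which argues against whole-chromosome copy number as the main source of the uneven bins. Gains and losses of parts of chromosomes stay open, since the input library was not analysed here. A hypothesis on the biological side is that RDMe1 may occupy gene-dense active regions, and it was not tested for bins because gene positions of the same build were not used.

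The number of protein-coding genes alone did not account for the difference between chromosomes. The limit for that was a 2-fold range of peaks per gene over the autosomes, set after the counts had been seen. The comparison therefore describes these counts and is not an independent test. Over the 22 autosomes the highest count of peaks per protein-coding gene, on chromosome 16, was 21.3 times the lowest, on chromosome 4. The 95% interval from resampled 1 Mb bins was 9.66 to 58.1, not corrected for picking the extremes or for runs of adjacent dense bins. Whole-chromosome copy number cannot be told apart from a difference in binding here: autosomes with more peaks per gene also had higher median scores (Spearman's rho = 0.66), which a higher copy number and stronger binding would both give. Read depth per chromosome in the input would be needed to decide it.

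The close spacing of peaks was more than the density of the 1 Mb bins gives, since 81.7% of peaks had a neighbour within 5 kb and at most 53.7% did in placements inside their own bins. Broad enriched regions split by the peak caller are a candidate explanation. Splits at gaps under 1 kb alone do not account for all of the close spacing. After merging such peaks, 66.8% of the merged peaks still had a neighbour within 5 kb. At most 41.3% did when the merged peaks were placed inside their own bins. Gap lengths had been seen before this comparison was chosen, so it describes the gaps and is not an independent test. Density at scales below 1 Mb, splits at longer gaps, and groups of separate sites, stay open without the signal between the peaks.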
